A study of Homo sapiens with 2 samples.

How the data were processed

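SW13 is an established line from a human adrenal adenocarcinoma. Per the labels' protocols, 10000000 cells were transfected at 80% confluence with 5 µg of plasmids for the murine long non-coding RNAs Mhrt779 and Hotair, using Lipofectamine in reduced serum medium, after growth in medium with 10% serum. The cells were collected 48 hours later. Total RNA was purified by direct lysis, and ribosome-associated RNA fragments were prepared with a ribosome profiling kit, in which nuclease digests RNA that ribosomes do not cover. Both preparations were made into libraries with that kit and read from both ends at 50 nt. The labels give 1 RNA sequencing library and 1 ribosome profiling library, so there are no replicates.

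The deposited table holds 23608 gene rows with 1 FPKM value per library, FPKM being fragments scaled by transcript length and by mapped fragments, as the authors computed them. It also holds the authors' log2 ratio of ribosome profiling over RNA sequencing, a test statistic, a p-value, a q-value, a significance call and a status for each row. The submitters' processing notes name TopHat2 2.0.8b, Bowtie2 2.0.0.6, SAMtools 0.1.18 and bedtools 2.16.1 and the builds hg19 and mm10, with no role or order. The program that wrote the table, its settings, its handling of reads that match several places and any scaling between the libraries are not given in the sources used here. Coordinates are those of the deposited table, with the first base written as 1. Its contig names are those of hg19, and a locus can span several overlapping genes. The Mhrt rows lie on sequences of their own.

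These steps bear on the values. FPKM divides by transcript length, so rows for very short RNAs reach very large values and take most of the FPKM sum. Reads from near-identical gene copies, from overlapping genes and from Mhrt forms that share sequence may have been divided between rows, and these rows are uncertain. A value of 0 can be an estimate that moved all reads to another row, so such a gene is only said to be listed at 0 and gets no fold. The number of reads behind each value is unknown, because FPKM keeps no depth and the low values gave no clean step, so no counting interval is given.

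The deposited log2 ratio equalled the log2 of the 2 FPKM values within 0.001 in 99.3% of the 10966 rows with a finite ratio other than 0. The deposited p-value matched a two-sided normal p of the statistic within 0.001 in 100% of the rows that have a finite ratio and the status OK. The standard error of a deposited log2 ratio was therefore taken as the size of the ratio over the size of the statistic. It is the authors' model error and holds no spread between cultures. Its median was 0.89 on the log2 scale over tested rows with the status OK.

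The ratio used here is log2((ribosome profiling FPKM + 1)/(RNA sequencing FPKM + 1)) minus its median over tested genes. A pseudocount of 1 FPKM understates the ratio of low genes. Tested genes have a mean FPKM of at least 10 over both libraries and a status other than FAIL or HIDATA, which left 2734 genes. Their median before centring was 0.39, so the median tested gene was 1.31-fold higher in ribosome profiling as deposited. Ratios of FPKM from libraries with different size and composition hold no absolute level, and every fold is relative to that median gene unless the authors' deposited table is named.

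With 1 library per group no p-value was computed. Genes at least 2-fold and at least 4-fold above or below the median gene were counted. For each gene list, the median ratio was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins, and a list was said to stand apart outside the 2.5 to 97.5 percentiles. Lists with fewer than 5 tested members got values only. This percentile describes these 2 libraries. The 34 gene lists, the tests and the naming rule were fixed before the data were examined. The rule took the 10 highest and 10 lowest ratios outside the small RNA list, the 5 highest and 5 lowest of those with a mean FPKM of at least 100, in each list the 3 members of highest mean FPKM and those of highest and lowest ratio, and HOTAIR, Hotair, Mhrt, MYH6, MYH7, SMARCA4, SMARCA2, MALAT1, NEAT1, ATF4, ACTB, GAPDH and EEF1A1. Correlations are across genes, which are not independent replicates.

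The random-list step was tested on simulated data made by shuffling the 2734 ratios. With 30 members, 72.5% of 200 lists shifted by 0.5 on the log2 scale and 99.5% of those shifted by 1 were placed above the band, against 4.5% of unshifted lists placed on either side. With 7 members the shares were 17.5% and 71.5%, against 7.0% of unshifted lists. The shuffling removed any link of the ratio with mean FPKM or between genes of a family. It also used fewer random lists than the main step, so these shares need not hold for the real lists.

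The alternatives were pseudocounts of 0.1 and 5, mean FPKM filters of 1 and 30 and no filter, status OK rows alone, ratios without centring, libraries rescaled to a sum of 1000000, small RNA genes left out, unmatched random lists, and for the deposited calls a q-value under 0.01 or a mean FPKM of at least 10. Chosen after seeing the data were protein-coding genes alone, genes listed at 0 left out, HOTAIR left out of its list, and a correction for coding share and transcript length that was run on protein-coding genes. Gene classes came from a RefSeq table, used for names only, which matched 22665 of the 23608 rows, and coding lengths from GENCODE 29. The list of mitochondrially encoded genes was not analysed here, because none of its symbols had a row in the deposited table. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.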

Results

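To determine which RNAs were recovered with ribosomes in cells that carried transfected murine long non-coding RNAs, ribosome profiling was set beside total RNA sequencing of SW13 cells, a human adrenal adenocarcinoma line. Each assay had 1 library and no replicates, so no value below has a replicate error. Of 23608 gene rows, 13990 were above 0 in RNA sequencing and 11423 in ribosome profiling, and 2734 passed the expression filter. The FPKM of all rows summed to 1846987 in RNA sequencing and 6457389 in ribosome profiling, and the read depth behind them is unknown. Folds are relative to the median tested gene on the log2(FPKM + 1) scale, except where the authors' deposited table is named.

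Whether the transfected RNAs were found with ribosomes was examined first. Mhrt, a long non-coding RNA that the mouse heart transcribes antisense to the myosin gene Myh7, was abundant in total RNA and far lower in ribosome profiling. The Mhrt779 row had 1851 FPKM in RNA sequencing and 210.5 FPKM in ribosome profiling, which is 11.5-fold below the median gene. HOTAIR, a long non-coding RNA of the HOXC cluster known to bind Polycomb proteins, had 612 FPKM in RNA sequencing and 2.92 FPKM in ribosome profiling, 205-fold below the median gene. The mRNA of the glycolytic enzyme GAPDH had 1192 and 1708 FPKM, and that of the actin ACTB had 759 and 885 FPKM.

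The 6 rows for forms of Mhrt, which share sequence and may share reads, ranged from 914 to 1914 FPKM in RNA sequencing. In ribosome profiling these rows ranged from 136 to 297 FPKM. They lay 7.87-fold to 11.5-fold below the median gene. Set among the 2259 tested protein-coding genes, Mhrt779 took rank 3 in RNA sequencing and rank 153 in ribosome profiling. Only 20 of these 2259 genes had a lower ratio than Mhrt779, and 1 had a lower ratio than HOTAIR. In the authors' deposited table the log2 ratio of Mhrt779 was -3.14 with a standard error of 1.14 and q = 0.174, and none of the Mhrt rows was called significant, with q-values up to 0.261. HOTAIR was called in the authors' deposited table, at a log2 ratio of -7.71 with a standard error of 1.33 and q = 5.7e-06. The log2 ratio of HOTAIR minus that of Mhrt779 was -4.58 in the authors' deposited table, with a combined standard error of 1.75 and a 95% interval from -8.00 to -1.15 if the errors are independent. For GAPDH and ACTB minus Mhrt779 the intervals in the authors' deposited table ran from 0.0071 to 7.30 and from -0.050 to 6.77, so that the first barely excluded 0 and the second did not. The HOTAIR row is the human gene, on chromosome 12 from 54356092 to 54370203 in hg19, and the values do not tell its own RNA from reads of the transfected murine Hotair. No row under the murine name was used here.

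**Figure D1:**
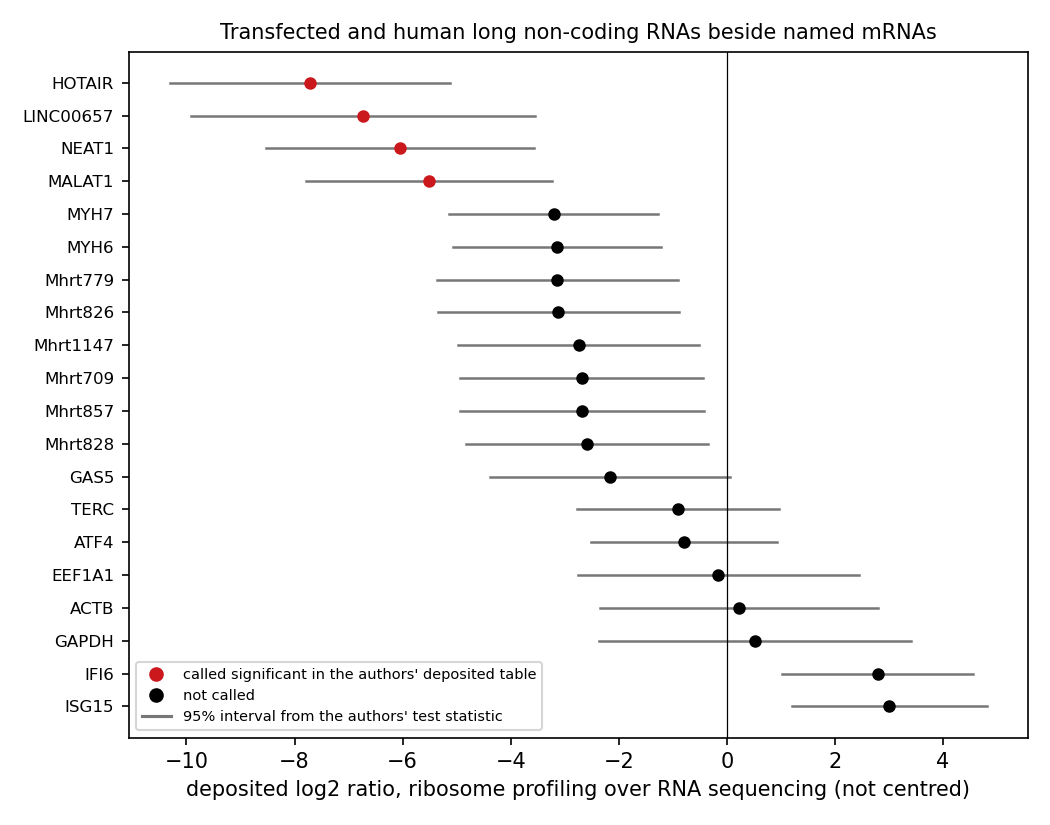
Deposited log2 ratio of ribosome profiling over RNA sequencing on the x axis, not centred, for the Mhrt rows, human long non-coding RNAs and named mRNAs, 1 library per assay, with lines for 95% intervals from the authors' test statistic and red points for significant calls. In the authors' deposited table HOTAIR at -7.71 lies left of Mhrt779 at -3.14, and GAPDH lies at 0.52.

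The myosin heavy chain genes MYH6 and MYH7, whose mouse locus is the origin of Mhrt, had ratios close to those of the Mhrt rows, with wide errors. MYH6 had 26.8 FPKM in RNA sequencing and 3.01 in ribosome profiling, 9.05-fold below the median gene, and MYH7 had 25.98 and 2.82 FPKM, 9.24-fold below. They lie on chromosome 14, MYH6 from 23851199 to 23877486 and MYH7 from 23881947 to 23904870 in hg19. In the authors' deposited table MYH7 differed from Mhrt779 by -0.066 in log2 ratio, with a combined standard error of 1.51. None of the other 15 cardiac sarcomere genes reached a mean FPKM of 10, and 11 of them were listed at 0 in both libraries.

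Human long non-coding RNAs were next compared with mRNAs. The list of nuclear and other long non-coding RNAs had a median 43.4-fold below the median gene, at percentile 0.01 of matched random lists, and 5 of its 6 tested members, HOTAIR among them, were at least 2-fold lower. Without HOTAIR, a choice made after the data were seen, the median of the other 5 lay 36.1-fold below at percentile 0.070. The size of the list's shift rests on the few members past the filter: its median log2 ratio was -5.44, against -6.14 with a pseudocount of 0.1, -3.79 with one of 5, -1.47 with a filter of 1 FPKM and -0.83 with no filter, each still below the band. MALAT1, a nuclear RNA on chromosome 11 from 65265233 to 65273939, had 390.3 FPKM in RNA sequencing and 8.54 in ribosome profiling, 53.7-fold below. NEAT1, the scaffold of paraspeckles, on chromosome 11 from 65190269 to 65194003, had 97.47 and 1.47 FPKM, 52.2-fold below. LINC00657 had 35.8 and 0.34 FPKM, and LINC00152 had 29.4 and 35.2 FPKM, which is 1.10-fold below the median gene. All of MALAT1, NEAT1 and LINC00657 were called in the authors' deposited table, at log2 ratios of -5.51, -6.05 and -6.73 with standard errors of 1.16, 1.27 and 1.62. TERC, the RNA component of telomerase, had a ratio of -0.91 with a standard error of 0.95 there and was not called.

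The host transcripts of small nucleolar RNAs, which are exported and rapidly degraded during translation, were also low. Their median lay 3.58-fold below the median gene at percentile 0.01, with 4 of 7 tested members at least 2-fold lower. GAS5 had 54.1 FPKM in RNA sequencing and 12.1 in ribosome profiling, SNHG8 had 42.8 and 54.1 FPKM, and SNHG9 had 22.5 FPKM and was listed at 0 in ribosome profiling. Genes named as long intergenic or antisense RNAs had a median 4.45-fold below, under every one of the random lists, with 5 of 9 at least 2-fold lower. LINC00657 and LINC00152 count both here and in the list of nuclear and other long non-coding RNAs. Their median log2 ratio was -2.15, against -1.36 with a filter of 1 FPKM and -0.45 with no filter, and that of the host transcripts -1.84, against -1.54 and -1.25, again below the band. With those filters the host transcripts lay lower than the list of nuclear and other long non-coding RNAs, the reverse of the main order. The difference between these lists was not tested. LINC00324 had 169 and 36.6 FPKM, C17orf76-AS1 had 129.9 and 37.5 FPKM, and RASAL2-AS1 had 17.4 and 36.5 FPKM. None of these, nor GAS5, SNHG8 or SNHG9, was called in the authors' deposited table. The q-values of GAS5, LINC00324 and C17orf76-AS1 in the authors' deposited table were 0.370, 0.292 and 0.238. By gene class, a split chosen after the data were seen, 14 of 23 tested long non-coding genes, HOTAIR included, were at least 2-fold below the median gene and 1 was at least 2-fold above. Among the 2259 tested protein-coding genes, 327 were at least 2-fold below and 227 at least 2-fold above.

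**Figure D2:**
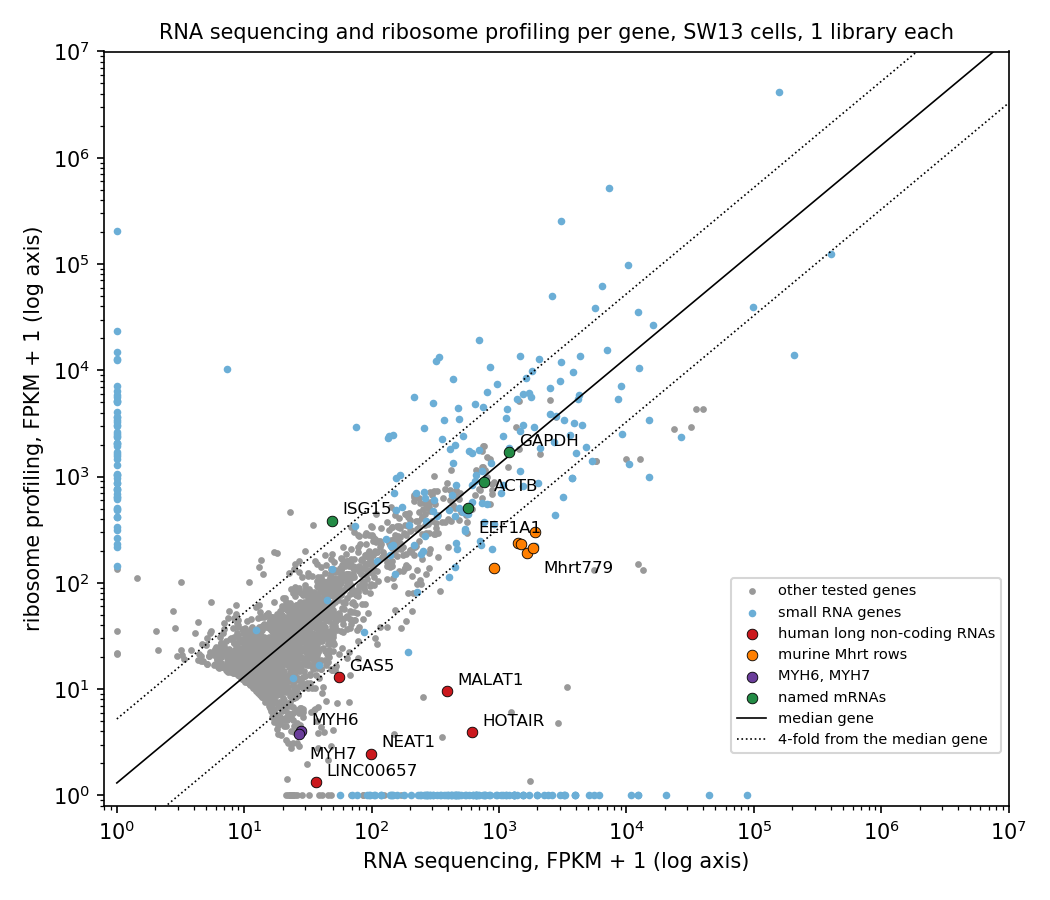
FPKM + 1 in RNA sequencing on the x axis against FPKM + 1 in ribosome profiling on the y axis, both on log axes, for the 2734 tested genes, 1 library each. The solid line is the median gene, dotted lines are 4-fold from it, and the Mhrt rows, HOTAIR, MALAT1 and NEAT1 lie below the lower dotted line.

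Among mRNAs, genes of the interferon response stood highest of the lists with a percentile. Their 6 tested members had a median 2.56-fold above the median gene, at percentile 99.9 of matched lists, and 3 were at least 2-fold higher. ISG15, a ubiquitin-like modifier that interferon induces, had 47.8 FPKM in RNA sequencing and 384 in ribosome profiling, 6.03-fold above the median gene. IFI6 had 28.9 and 199 FPKM, 5.12-fold above, and the restriction factor IFITM3 had 81.7 and 163 FPKM, 1.52-fold above. Of the 21 members with a mean FPKM of at least 1, 19 lay above the median gene. ISG15 and IFI6 were not called in the authors' deposited table, at log2 ratios of 3.01 and 2.79 with standard errors of 0.92 and 0.90 and q-values of 0.067 and 0.104.

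Nuclear-encoded genes of oxidative phosphorylation were also higher in ribosome profiling, relative to the median gene. Their 69 tested members had a median 1.47-fold above it, at percentile 99.99, with 18 at least 2-fold higher, 1 at least 2-fold lower and 50 between. COX6B1, a subunit of cytochrome c oxidase, had 98.5 FPKM in RNA sequencing and 341 in ribosome profiling, 2.62-fold above. ATP5I, a subunit of ATP synthase, had 152 and 483 FPKM, 2.41-fold above, and NDUFS7 of complex I had 23.7 and 133 FPKM, 4.15-fold above. NDUFA5, the lowest member, had 16.9 and 9.62 FPKM.

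Extracellular matrix and secreted proteins had a median 1.53-fold above the median gene at percentile 98.5, with 3 of 13 tested members at least 2-fold higher and 1 lower. The lysosomal protein precursor PSAP had 46.8 and 166 FPKM in the RNA sequencing and ribosome profiling libraries, GRN had 12.4 and 52.6 FPKM, and the protease inhibitor TIMP2 had 18.5 and 11.5 FPKM. Aminoacyl-tRNA synthetases, which charge tRNAs, had a median 1.34-fold above at percentile 98.6, with 2 of 22 at least 2-fold higher and none 2-fold lower. FARSB had 5.46 and 18.7 FPKM, AARS had 25.8 and 51.8 FPKM, and QARS had 11.4 and 9.38 FPKM. Proteasome subunits had a median 1.36-fold above at percentile 98.0, with 3 of 30 at least 2-fold higher and none 2-fold lower. PSMB1 had 132 and 369 FPKM and PSMC1 had 24.0 and 74.99 FPKM. Mitochondrial ribosomal proteins had a median 1.17-fold above at percentile 97.8, with 11 of 49 at least 2-fold higher and 4 lower, and MRPL27 with 4.42 and 32.8 FPKM and MRPL10 with 16.5 and 4.03 FPKM marked their extremes. Of 13 alternative settings, 10 kept the synthetases outside the band, 8 the proteasome and 6 the mitochondrial ribosomal proteins, whose median was -0.11 with a filter of 30 FPKM. The setting without centring is among the 13 and cannot change a percentile.

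Against random lists drawn from all tested genes, the only list of protein-coding genes placed low was that of polyamine and frameshift regulated genes. Its 7 tested members had a median 1.86-fold below the median gene at percentile 2.47, barely past the limit, with 3 at least 2-fold lower. SRM, which makes spermidine, had 17.1 FPKM in RNA sequencing and 3.23 in ribosome profiling, 5.60-fold below. OAZ1, the antizyme whose synthesis needs a ribosomal frameshift, had 78.1 and 37.6 FPKM, and the spermine synthase SMS had 62.6 and 47.9 FPKM. This placement was lost with a pseudocount of 5, with status OK rows alone and with unmatched lists. Against protein-coding genes alone it was kept. There, cytosolic ribosomal proteins, translation factors with 5-prime TOP mRNAs, immediate-early mRNAs and replication-dependent histones were placed low as well.

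**Figure D3:**
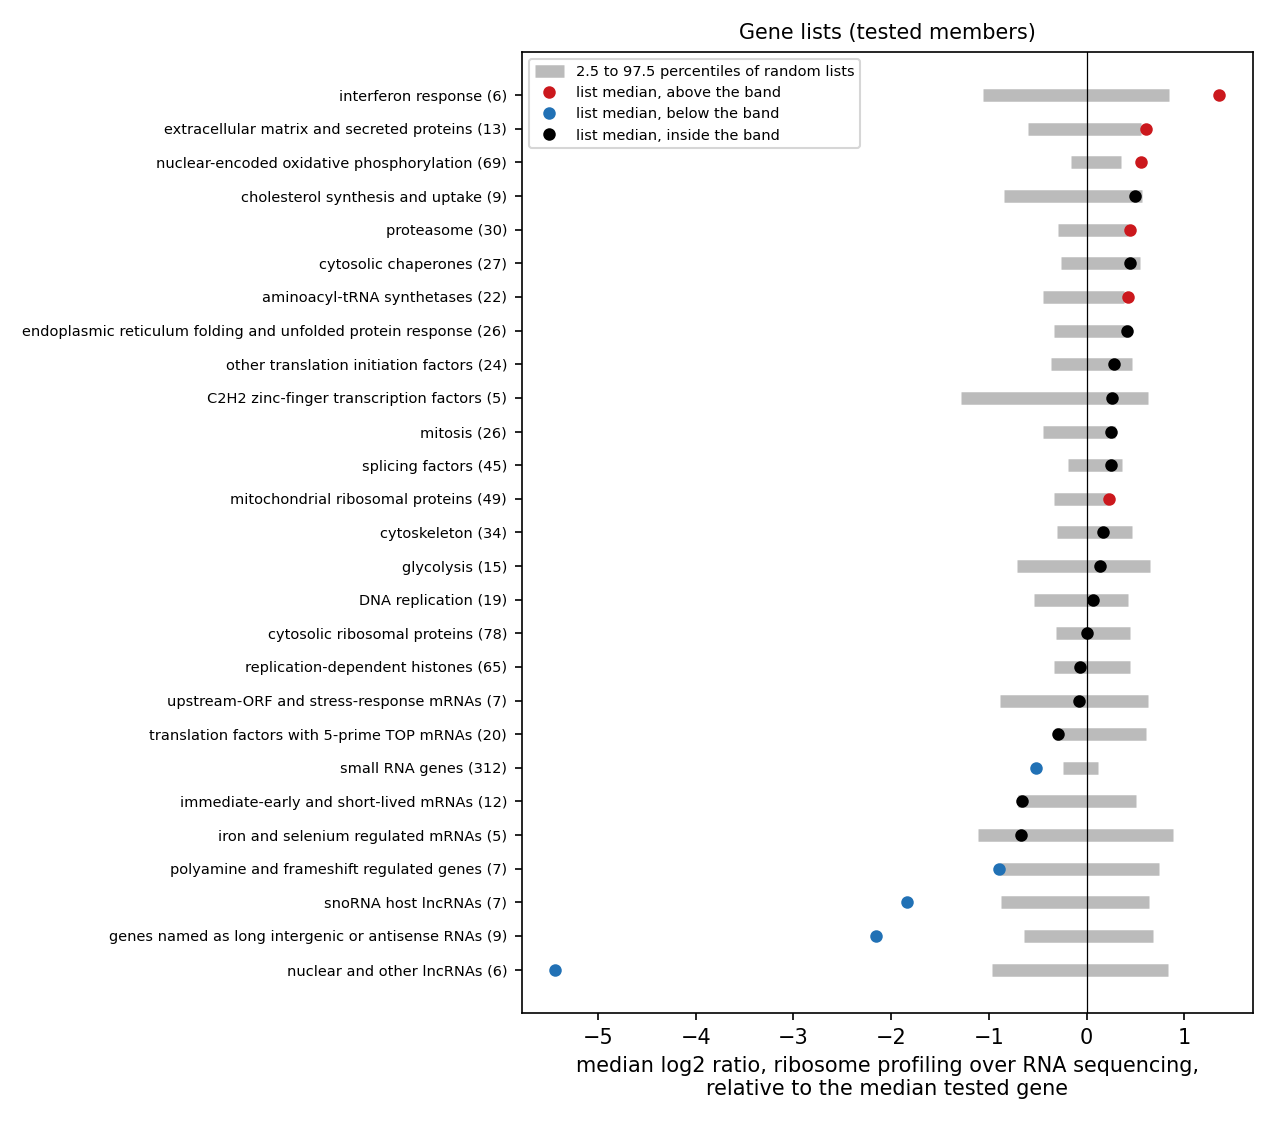
Median log2 ratio of ribosome profiling over RNA sequencing relative to the median tested gene on the x axis, for 27 gene lists with their number of tested members. Grey bars span the central 95% of 10000 random lists, and 6 lists lie above and 5 below their bar.

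Cytosolic ribosomal proteins and translation factors lay inside the band of matched random lists drawn from all tested genes. The 78 tested cytosolic ribosomal proteins had a median log2 ratio of 0.0054 at percentile 20.2, with 3 at least 2-fold higher and 9 lower. Those 9 include RPL21 and RPL13A, the latter listed at 0 in ribosome profiling. Summed with their copies RPL21P28 and RPL13AP5 after the data were seen, they had log2 ratios of 0.34 and 0.44. RPL8 had 411 and 602 FPKM and RPL37A had 417 and 603 FPKM. Translation factors with 5-prime TOP mRNAs, a class that growth signalling controls through a pyrimidine tract, had a median of -0.29 at percentile 3.3, with none of 20 at least 2-fold higher and 4 lower. The elongation factors EEF1A1 and EEF2 had 566 and 506 FPKM and 284 and 208 FPKM. With small RNA genes left out of the background, both lists lay below the band, at percentiles 1.09 and 0.59, and with protein-coding genes alone at 0.11 and 0.40. Other translation initiation factors had a median of 0.28 at percentile 84.0, with EIF3J at 11.4 and 57.6 FPKM and the translation repressor EIF4EBP1 at 16.0 and 5.26 FPKM.

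Protein folding genes lay above the median gene without leaving the band. Endoplasmic reticulum folding and unfolded protein response genes had a median of 0.42 at percentile 96.6, with 6 of 26 at least 2-fold higher and 2 lower, and the chaperone HSPA5 had 47.5 and 185.5 FPKM. This list passed the upper limit under 5 of the 13 alternative settings. Cytosolic chaperones had a median of 0.44 at percentile 90.2, with HSP90AA1 at 389 and 866 FPKM, and cholesterol synthesis and uptake genes a median of 0.49 at percentile 95.2, with SQLE at 4.78 and 20.2 FPKM and FDPS at 30.3 and 84.3 FPKM.

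Immediate-early and short-lived mRNAs had a median of -0.67 at percentile 3.2, with 3 of 12 at least 2-fold lower and 1 higher, and lay below the band at percentile 2.20 with small RNA genes left out, but at percentile 40.8 with a filter of 1 FPKM. The transcription factor EGR1 had 23.2 and 4.13 FPKM, FOSL1 had 66.2 and 44.8 FPKM, and the matricellular protein CTGF had 7.77 and 37.2 FPKM. Upstream-ORF and stress-response mRNAs had a median of -0.082 at percentile 38.9. Of these, ATF4, whose upstream reading frames hold back its translation in unstressed cells, had 36.8 and 21.3 FPKM and was 2.22-fold below. In the authors' deposited table ATF4 was not called, at a log2 ratio of -0.79 with a standard error of 0.88. ASNS, a target of ATF4, had 20.1 and 70.8 FPKM. It was called in the authors' deposited table at a log2 ratio of 1.82 with a standard error of 0.51. Iron and selenium regulated mRNAs had a median of -0.67 over 5 members at percentile 7.1, with the ferritin chain FTL at 148 and 91.7 FPKM.

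A further 6 lists lay inside the band. The medians were 0.14 for glycolysis at percentile 53.2, 0.25 for splicing factors at percentile 85.8, 0.062 for DNA replication at percentile 68.2, 0.25 for mitosis at percentile 95.5, 0.16 for the cytoskeleton at percentile 61.6 and -0.066 for replication-dependent histones at percentile 22.7. With protein-coding genes alone, histones lay below the band at percentile 0.020. The enzymes PKM and ENO1 had 266 and 506 FPKM and 298 and 666 FPKM. The splicing factor SRSF1 had 25.03 and 9.38 FPKM, the replicative helicase subunit MCM7 had 57.0 and 133 FPKM, the apoptosis inhibitor BIRC5 had 17.5 and 6.08 FPKM, and the histone gene HIST1H4K, which shares sequence with other histone genes, had 745 and 1948 FPKM. C2H2 zinc-finger transcription factors had 5 tested members and a median of 0.26 at percentile 88.9, and with a filter of 1 FPKM, which reached 313 members, their median was -0.40 at percentile 0.75.

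Small RNA genes took 79.7% of the FPKM sum in RNA sequencing and 96.5% in ribosome profiling. RNA5-8S5, a ribosomal RNA of the large subunit, had 157223 FPKM in RNA sequencing and 4180970 in ribosome profiling, which is 64.7% of that library's sum. The 312 tested small RNA genes went both ways, with 114 at least 2-fold higher and 139 lower, a median of -0.52 and 160 of them listed at 0 in 1 library. The median was below all random lists, and without the genes listed at 0 it was 0.22, at percentile 99.9. Of the 122 box C/D small nucleolar RNAs (SNORD), 59 were at least 2-fold higher and 38 lower, and these counts include 33 listed at 0 in RNA sequencing and 28 listed at 0 in ribosome profiling. Of the 76 microRNA genes, 19 were higher and 45 lower, of which 14 and 41 were listed at 0 in RNA sequencing and in ribosome profiling. The 2 Y RNAs and 3 vault RNAs were all lower, with 1 of each listed at 0 in ribosome profiling. RNU12, of the minor spliceosome, had 7275 and 524246 FPKM, RNY5 had 400225 and 124864 FPKM, and VTRNA1-2, named after its values were seen, had 205821 and 14023 FPKM.

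Across all tested genes, 358 were at least 2-fold above the median gene and 538 at least 2-fold below, and 133 and 268 were at least 4-fold above and below. These counts include 59 genes listed at 0 in RNA sequencing and 125 listed at 0 in ribosome profiling. The 4-fold counts were 73 and 151 without genes listed at 0 and 44 and 151 without small RNA genes, and with no expression filter the 2-fold counts were 2332 higher and 2180 lower. Of the genes past 2-fold, 39.96% were higher. As deposited and without centring, 645 were higher and 389 lower, so that 62.4% were higher, and with each library rescaled to a sum of 1000000 the numbers were 107 and 1647, or 6.10% higher. Pearson's r across the tested genes was 0.33 and Spearman's rho 0.40. Across the 2422 tested genes that are not small RNAs, r was 0.68 and rho 0.58.

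The 10 highest and 10 lowest ratios outside the small RNA list included gene copies, short RNAs and other genes. Among the lowest were HOTAIR and the GAGE12D cancer-testis antigen gene with 1761 FPKM in RNA sequencing and 0.38 in ribosome profiling, while its near-identical neighbour GAGE8 was listed at 0 in RNA sequencing and had 954 FPKM in ribosome profiling. MTRNR2L10, MTRNR2L6, MTRNR2L3, MTRNR2L4 and MTRNR2L8, nuclear copies of a mitochondrial ribosomal RNA, were 133-fold to 794-fold below the median gene. No symbol on the list of mitochondrially encoded genes had a row, so these values cannot be told from reads of the mitochondrial RNA itself. BCYRN1 had 344 FPKM, SNAR-G1 had 169.8 FPKM and GUSBP9 had 125 FPKM in RNA sequencing, and each was listed at 0 in ribosome profiling. Among the highest, GSG1L had 22.0 and 460 FPKM, the copper transporter family member SLC31A2 had 1.76 and 52.8 FPKM, the row shared by XAGE2 and XAGE2B had 2.17 and 99.98 FPKM, and C15orf40 had 1.03 and 33.9 FPKM. H3F3AP4, GAGE12G and LOC649330 were near 0 in RNA sequencing and had 134, 111 and 34.5 FPKM in ribosome profiling, and CETN2 and PAM16, listed at 0 in RNA sequencing, had 20.7 and 20.3 FPKM. Of the abundant genes, CHD3, ARIH1 and CXXC4 were 7.80-fold, 8.05-fold and 8.64-fold above the median gene.

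Of 4849 rows with the status OK, 63 were called significant in the authors' deposited table, 20 higher and 43 lower in ribosome profiling. The lower calls included all 9 MTRNR2L rows, 5 NBPF, 4 GOLGA, 4 SNAR and 2 SPDYE rows, which are multicopy families, and 4 long non-coding genes. The higher calls included 6 small RNA genes and 14 protein-coding genes. By the same gene classes, 20 of the lower calls were protein-coding. BTF3L4, named after its value was seen, had the lowest q-value among the higher calls in the authors' deposited table, 1.8e-06 at a log2 ratio of 3.86 with a standard error of 0.64.

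Genes tied to the transfected RNAs or to the origin of the line were mostly under the filter. Of the 24 SWI/SNF chromatin remodelling subunits 2 were tested, SMARCB1 with 10.1 and 13.5 FPKM and ACTL6A with 9.52 and 19.3 FPKM. The ATPase SMARCA4, a known partner of Mhrt, had 3.99 FPKM in RNA sequencing and 0.68 in ribosome profiling, and SMARCA2 had 1.72 and 1.75 FPKM. Of the Polycomb and HOTAIR partners, KDM1A had 15.1 and 18.5 FPKM and RBBP7 had 18.3 and 39.5 FPKM. Of the HOX genes 3 were tested, with HOXB2 at 15.8 and 8.03 FPKM and HOXB7 at 8.10 and 17.8 FPKM. Adrenocortical steroid synthesis genes were above 0 in RNA sequencing in 5 of 15 cases, and the 1 tested, the electron donor POR, had 15.9 and 20.7 FPKM. Of 21 markers of blood, endothelial and fibroblast cells, 13 were listed at 0 in both libraries. The 2 tested were CD68 with 17.6 and 14.6 FPKM and the beta-globin gene HBB with 691 and 766 FPKM.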

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

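The choices of protein-coding genes alone, of leaving out genes listed at 0, of leaving out HOTAIR and of the correction for coding share were made after seeing the data. No paired analysis was possible because each assay had 1 library. The oxidative phosphorylation, interferon, extracellular matrix and the 3 long non-coding RNA lists kept their side of the band under every alternative that left at least 5 members. For ratios without centring this was fixed in advance, because a common shift changes no percentile. The long non-coding RNA lists overlap in part, so their placements are not independent. The placements of the polyamine and mitochondrial ribosomal lists lie close enough to the limits to depend on the random draw. Of the comparisons of a named gene with an alternative, 582 left its ratio within 1.5-fold. Another 195 moved the ratio further without turning a ratio of at least 2-fold. A further 6 changed the sign of such a ratio, all under the rescaling. The filters, the status, the centring and the omission of small RNA genes move every ratio by the same amount, through the median gene. Under these settings the tally says nothing about single genes. The read depth is unknown, so what it limits could not be computed, and the cause of the changes below was not tested except where the set of genes itself changed.

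With a pseudocount of 0.1, Pearson's r was 0.14, and the mitochondrial ribosomal list, at 0.22, was inside the band. With a pseudocount of 5, r was 0.48, the endoplasmic reticulum list was above the band at 0.39 and the polyamine list inside it at -0.75.

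With a filter of 1 FPKM and with no filter the median gene lay at -0.16 and -0.28 before centring, -0.55 and -0.67 from its main value, so that the ratios of abundant genes lie higher there by construction. With no filter the medians of the TOP, immediate-early, iron and selenium, histone, small RNA and upstream-ORF lists, below 0 in the main setting, were above 0, at 0.43, 0.39, 0.021, 0.54, 0.19 and 0.018. With a filter of 1 FPKM, which admits more genes, 1681 genes were at least 2-fold higher and 2127 lower, 343 and 647 at least 4-fold, r was 0.64 and Spearman's rho 0.58. The proteasome was inside the band at 0.91, the endoplasmic reticulum list at 0.81 and cholesterol synthesis at 0.73 were above it, and zinc-finger factors reversed to -0.40. With a filter of 30 FPKM, 182 genes were at least 2-fold higher and 261 lower, 178 at least 4-fold lower, r was 0.061 and rho 0.27. The synthetases at 0.41 were inside the band, the endoplasmic reticulum list at 0.68 above it, and the mitochondrial ribosomal list reversed to -0.11. With no filter, 2332 genes were at least 2-fold higher and 2180 lower, 399 and 544 at least 4-fold, r was 0.72 and rho 0.69, and the endoplasmic reticulum list at 0.92 and cholesterol synthesis at 0.85 were above the band.

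With status OK rows alone, the immediate-early list was below the band at -0.88 and the polyamine list inside it at -0.91. As deposited and without centring, 645 genes were at least 2-fold higher. Rescaling each library to a sum of 1000000 set the median tested gene at -1.19, which by construction shifts the ratios. The shift is unequal between genes, because the pseudocount was added after the rescaling. There, 107 genes were at least 2-fold higher and 1647 lower, 81 and 576 at least 4-fold, and r was 0.46. The synthetases at -0.86 and the mitochondrial ribosomal list at -0.98 were inside the band and the endoplasmic reticulum list at -0.84 above it. The ratio changed sign to -0.14 for ATP5I, -0.015 for COX6B1, -0.020 for FARSB, -0.31 for FDPS, -0.32 for PSMB1 and -0.15 for PSMC1.

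With small RNA genes left out, 44 genes were at least 4-fold higher and 151 lower, r was 0.68 and rho 0.58. Ribosomal proteins at -0.0054, TOP factors at -0.30 and the immediate-early list at -0.68 were below the band, and the mitochondrial ribosomal list at 0.22 and the proteasome at 0.43 inside it. Against unmatched lists, the synthetases at 0.43, the mitochondrial ribosomal list at 0.23 and the polyamine list at -0.90 were inside the band and cytosolic chaperones at 0.44 above it.

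With protein-coding genes alone, 209 genes were at least 2-fold higher and 347 lower, 34 and 97 at least 4-fold. Ribosomal proteins at -0.033, TOP factors at -0.33, the immediate-early list at -0.70 and histones at -0.10 were below the band, and the mitochondrial ribosomal list at 0.19 and the proteasome at 0.40 inside it. With genes listed at 0 left out, 73 genes were at least 4-fold higher and 151 lower, TOP factors at -0.33 and the immediate-early list at -0.70 were below the band, the proteasome at 0.41 inside it, and small RNA genes reversed to 0.22. The correction for coding share, run on protein-coding genes, moved no list across a limit that it had not already crossed with protein-coding genes alone. After it, ribosomal proteins at 0.030, TOP factors at -0.27, the immediate-early list at -0.53 and histones at -0.15 were below the band, and the mitochondrial ribosomal list at 0.28 and the proteasome at 0.47 inside it. A q-value under 0.01 left 32 calls in the authors' deposited table.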

Other observations

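The sums over families, copies and loci, the tests on MYH6, MYH7 and HBB and the correction for coding share were all chosen after the ratios had been seen. For the correction alone, the outcome that would speak for or against it was written before its result was known.

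Families with many copies that were low in ribosome profiling, picked after their values were seen, were also low when all rows of a family were summed, in NBPF, GOLGA6 and GOLGA8. In SPDYE, GUSBP and NPIP every row was listed at 0 in ribosome profiling, so that their sums could only be low. The summed NBPF rows had 239.8 FPKM in RNA sequencing and 16.5 in ribosome profiling, and all 13 rows were lower in ribosome profiling. The GOLGA8 rows summed to 28.1 and 0.27 FPKM, and the GUSBP rows to 211 FPKM and a listed 0. The GAGE rows summed to 17406 and 27685 FPKM, 0.28 above the median gene on the log2 scale. Some pairs of a gene and its processed copy, also picked after the values were seen, had opposite extremes. H3F3A had 84.4 FPKM in RNA sequencing and 0.0096 in ribosome profiling and H3F3AP4 had 0.0025 and 134 FPKM, while their sums of 84.4 and 134 FPKM lay 0.27 above the median gene. RPL21 had 85.1 and 0.0066 FPKM and its copy RPL21P28 had 12.4 and 163 FPKM, with a summed ratio of 0.34. The sum of GAGE12D and GAGE8 stayed low, at -1.27. Of 24 genes outside the small RNA list that were listed at 0 in 1 library, 21 of them in ribosome profiling, 4 had another row at the same locus with the same first 4 letters, and 2 of these came within 2-fold of the median gene when such rows were summed.

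The signal of MYH6 and MYH7 in RNA sequencing may come from reads of the transfected murine Mhrt RNA, which shares sequence with myosin genes. This stays open: MYH7 differed from Mhrt779 by -0.066 in log2 ratio in the authors' deposited table, but that closeness prompted the hypothesis and its combined standard error of 1.51 allows a wide range. Expression of the cardiac sarcomere genes in these cells is argued against by their other members, of which 0 of 15 reached a mean FPKM of 10. Low translation of MYH6 and MYH7 mRNA made without the rest of the sarcomere stays open, because the table holds no reads to place.

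HBB had 691 FPKM in RNA sequencing and 766 in ribosome profiling, a deposited log2 ratio of 0.15 with a standard error of 1.10 in the authors' deposited table, and ranked 25 and 24 among the 2259 tested protein-coding genes. It lies on chromosome 11 from 5246696 to 5248301 in hg19. RNA from blood cells as its source stays open. It would bring alpha-globin, and HBA1 and HBA2, listed at 0, came to 0% of HBB in RNA sequencing, but in this table a 0 of near-identical copies can be a failed estimate. Whether the signal comes from the genome of these cells or from globin sequence carried by a plasmid was not tested, since the plasmid sequences are not given in the sources used here.

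The higher ratios of oxidative phosphorylation and interferon genes might reflect a larger coding share of their transcripts, because ribosomes protect coding sequence while RNA sequencing covers whole transcripts. The median coding shares argue against this. They were 56.9% in the oxidative phosphorylation list and 55.2% in the interferon list, against 59.9% over all corrected genes. After correction of the protein-coding genes for coding share and transcript length, the oxidative phosphorylation list was at percentile 99.99. Its median was 0.61 after and 0.56 before. The interferon list was at percentile 99.95, with medians of 1.40 and 1.36. The slope on log2 coding share was 0.044 with a standard error of 0.032. A correction with so small a slope could hardly move a list, so the percentiles after it add little to the question. Fragments confined to coding sequence would make the ratio rise in proportion to coding share. The slope shows almost no such rise, so these values do not show that the ribosome profiling fragments lay in coding sequence. Where they lay could not be checked, since FPKM keeps no positions. Transfection itself as the biological origin of the interferon ratios was not tested, since there is no library of untransfected cells.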
